A study of Homo sapiens with 9 samples.

How the data were processed

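HEYA8 cells, a human ovarian cancer cell line that the labels call high-grade serous and wild type, were grown in DMEM with serum. They received DMSO, sunitinib or compound 32 for 24 h. Each treatment had 3 samples, and all 9 samples carry the same day in the labels. The doses of both compounds, and how compound 32 relates to sunitinib, are not given in the sources used here. RNA was extracted with TRIzol, polyadenylated RNA was enriched on oligo(dT) beads, and cDNA was made with random hexamers, per the labels' protocols.

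The deposited table holds raw counts of reads per gene, as whole numbers, for 58735 genes in 9 columns, 1 per sample. Per the submitters' processing notes, the authors used fastp, HISAT2 2.0.5, featureCounts, DESeq2 and edgeR. The notes give no role for each tool and list a mouse build beside the human build hg38. All 58735 gene identifiers, names and coordinates in the table were those of GENCODE release 29 on that human build (GRCh38). Whether reads were counted by strand, and how reads that map to several genes were treated, is not given in the sources used here. Each count column was matched to its sample by the name given in that sample's label.

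Total counts per library, summed over all genes, ran from 15498101 to 18006171. A total of 26930 genes had no count in any library. Genes were kept by edgeR's filterByExpr with the treatment as the group, which left 15232 genes. Counts were scaled by TMM factors, which lay between 0.983 and 1.051. Values in CPM, counts scaled to a common library size, use these factors. The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with robust estimation and a group-means model over all 9 libraries. The 3 treatments therefore shared 1 estimate of the spread, on 6 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The ± after a log2 fold change is a standard error (SE) from the same test, and n is 3 libraries per group throughout. The series text calls the sunitinib and DMSO samples biological replicates. It does not say so of the compound 32 samples, for which p-values measure the spread between these samples, which may be technical.

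Before the data were examined, the comparisons, the tests, the rule for named genes, most alternatives and 38 gene lists were fixed. They cover DNA repair by pathway, the cell cycle, stress responses, metabolism, signalling, kinases bound by sunitinib, markers of other cell types and signs of RNA quality. Of 998 symbols, 975 genes were found in the table and 871 passed the count filter. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The adjusted p is over the 38 lists of a comparison. The same test with an estimated correlation, and fry, were alternatives. For each list the members called over all genes were counted, and again with p-values adjusted over the list alone. Intervals of 95% for the difference between compounds come from a linear model of each library's mean log2 CPM over a list, on the same 9 libraries.

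The rule for named genes took, per comparison, the 8 protein-coding genes with the largest rise and the 8 with the largest fall. These had to be called, to have a mean of at least 5 CPM and to show no overlap between the groups. It added the 3 members with the smallest p of each called list and of each DNA repair list, the kinases bound by sunitinib, and 6 genes with opposite calls for the compounds. Any other gene is marked as chosen after its values were seen.

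Counts for 15232 genes were simulated from the real means, library sizes and dispersions, with 200 genes changed and 1 list of 30 genes shifted. For sunitinib against DMSO the count test recovered 59.7% of genes changed by 1.5-fold, 82.1% at 2-fold and 93.9% at 4-fold. For compound 32 against DMSO these shares were 61.2%, 79.1% and 92.4%, and for compound 32 against sunitinib 55.2%, 83.6% and 97%. Between 11 and 13 of 15002 unchanged genes were called. In each simulated comparison camera called the shifted list and 0 of 20 unchanged lists. Each gene was drawn independently and the lists were random genes, so the simulation does not cover correlation between the members of a list. Nor does it cover a deviation that many genes of a library share.

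Replicates were compared before use. Pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 1.82, so no sample was counted as a copy of another. For the pairs with sunitinib replicate 3 it was 41.3 and 40.3, and for all other pairs at most 3.04. The shared estimate of the spread therefore included a library that stood apart from its group. Alternatives covered other scalings, other filters on low counts, DESeq2 1.42.0, limma voom, a block for the number in the sample titles, only the 6 libraries compared, other thresholds, and leaving out each library in turn. Added after seeing the data were compound 32 against DMSO and the numbers of members called per list without sunitinib replicate 3, upper-quartile factors for the lists, and a within-group correction for transcript length and GC content. That correction fitted each library's deviation from its group mean by loess with a span of 0.5. It narrowed the spread within groups but left the group means in place, so it could not take a library's bias out of its group's mean.

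Of 129 named genes, 6 share at least 10% of their exon bases with a tested gene on the other strand, and 10 share at least 10% of their 50-base words with another gene. Their counts are uncertain, because strand and the treatment of shared reads are unknown. On the other strand these were CCNE2 (37% of its exon bases, with INTS8), LIG3 (29.1%, with RFFL), MSH6 (16.2%, with FBXO11), CCDC92 (11.9%, with DNAH10), FANCF (11.3%, with GAS2) and SHLD2 (10.9%, with GLUD1). The words in common made up 74.6% of HIST1H2BK, 72.5% of HSPA1A (with HSPA1B), 53% of SHLD2, 51.4% of TCAF2 and 29.4% of RRM2. They made up 26% of RPL3, 25.4% of UHRF1, 17.5% of HSP90AA1, 16.3% of RPL13A and 11.1% of BNIP3.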

Results

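The transcriptome of HEYA8 ovarian cancer cells was measured after 24 h with DMSO, with sunitinib, an inhibitor of several receptor tyrosine kinases, or with compound 32, in 3 libraries each. The series asks whether sunitinib suppresses DNA repair pathways, in a study of its synergy with the DNA-damaging drug cisplatin, and how compound 32 regulates the same cells. No sample received cisplatin. Library totals were 15.6 to 16.9 M counts for DMSO, 15.5 to 18 M for sunitinib and 15.7 to 17 M for compound 32.

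Replicates of DMSO and of compound 32 were close, with Pearson correlations of log2 CPM across genes, which are not independent replicates, between 0.9915 and 0.9922. In the sunitinib group replicates 1 and 2 correlated at 0.9932, but replicate 3 at 0.9815 and 0.9811 with them. Sunitinib replicate 3 held 7.44% of its counts in ribosomal protein genes and 5.36% in mitochondrial genes. The other 8 libraries held 4.05 to 4.9% and 3.42 to 3.92%. The first principal component took 53.3% of the variance and the second 16.4%.

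Sunitinib lowered the genes of DNA replication and raised targets of ATF4, a transcription factor of stress responses. The steepest falls against DMSO were in E2F2 (log2 fold change -3.51 ± 0.23) and E2F8 (-2.47 ± 0.12), transcription factors of the G1/S programme, and in FAM111B (-3.25 ± 0.10) and ZNF367 (-2.42 ± 0.10). MCM10 (-2.33 ± 0.08) and ORC1 (-2.13 ± 0.08), which build replication origins, also fell. So did CLSPN (-2.24 ± 0.08), an adaptor of the replication checkpoint, and CDC25A (-2.14 ± 0.09), a phosphatase that activates cyclin-dependent kinases. The largest rises were in DDIT4 (2.71 ± 0.11), a stress-induced brake on mTOR signalling, ASS1 (2.56 ± 0.18), SLC6A9 (2.54 ± 0.18) and PCK2 (2.48 ± 0.09). IL1B (2.47 ± 0.15), OSCAR (2.35 ± 0.12), ULBP1 (2.35 ± 0.16), a ligand of a natural killer cell receptor, and TXNIP (2.29 ± 0.13) completed the top genes. In edgeR, the adjusted p of all these genes was at most 1.49e-06, that of ASS1.

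In total, edgeR called 3090 genes higher and 3036 lower under sunitinib, 40.2% of the genes tested. At 2-fold or more these were 864 higher and 339 lower. The balance of calls depends on the scaling, since upper-quartile factors gave 3952 higher and 2316 lower. Without sunitinib replicate 3 the counts were 3908 and 4096.

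All 35 measured genes of DNA replication and S phase fell under sunitinib, with a median log2 fold change of -1.39 (camera adjusted p = 6e-27). MCM4, a subunit of the replicative helicase, went from 590.6 ± 6.60 CPM (SD, n = 3) in DMSO to 157.9 ± 5.48 CPM, and UHRF1 changed by -2.05 ± 0.07. Among genes of mitosis 37 of 39 fell, with a median of -0.90 (camera adjusted p = 4.48e-20), including MYBL2 (-1.33 ± 0.06), ANLN (-1.30 ± 0.07) and the cyclin CCNA2 (-1.21 ± 0.06). With p-values adjusted over the list alone, the same numbers fell in both lists, 35 and 37. With an estimated correlation the camera adjusted p was far larger, 0.00282 for S phase and 0.0345 for mitosis. MCM4 (ENSG00000104738) lies on chromosome 8 from 47960185 to 47978160 (GRCh38), E2F2 (ENSG00000007968) on chromosome 1 from 23506430 to 23531220, and DDIT4 (ENSG00000168209) on chromosome 10 from 72273920 to 72276036.

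The list of all DNA repair pathways fell under sunitinib, with 64 of 142 members lower, 22 higher and a median of -0.22 (camera adjusted p = 2.59e-06), which was -0.14 with upper-quartile factors. In counts adjusted over the list alone, 71 were lower and 23 higher. Homologous recombination and Fanconi anaemia genes were lower in 29 of 46 cases and higher in 2, median -0.69 (camera adjusted p = 6.01e-10). BRIP1, a helicase that binds BRCA1, fell from 30.7 ± 1.52 to 9.92 ± 0.11 CPM (SD, n = 3). XRCC2 changed by -1.68 ± 0.09 and POLQ, the polymerase of theta-mediated end joining, by -1.41 ± 0.09. Of the mismatch repair genes 11 of 18 fell and 2 rose, median -0.73 (camera adjusted p = 3.94e-05). MSH6, which recognises mismatches, changed by -1.42 ± 0.06, and the clamp loader genes RFC3 and RFC5 by -1.35 ± 0.08 and -1.14 ± 0.07. FBXO11, which overlaps MSH6 on the other strand, changed by -0.15 ± 0.08 (edgeR adjusted p = 0.157).

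Among DNA damage checkpoint genes 15 of 21 fell and 1 rose, median -0.61 (camera adjusted p = 1.55e-06), with TOPBP1 at -0.81 ± 0.06 beside CLSPN and CDC25A. When adjusted over the list alone, 32 genes of homologous recombination, 11 of mismatch repair and 15 of the checkpoint were lower. These 4 list calls held with an estimated correlation, at camera adjusted p of 0.0345 for all repair pathways, 0.00282, 0.0393 and 0.0125. Other repair pathways were not called as lists. Of 27 nucleotide excision repair genes 8 rose and 6 fell, median 0.01 and -0.03 without sunitinib replicate 3 (camera adjusted p = 0.861 and 0.586), with LIG1 at -0.89 ± 0.08, RPA1 at -0.53 ± 0.06 and UVSSA at 0.55 ± 0.11. Of 23 genes of base excision and single-strand break repair 6 rose and 8 fell, median -0.17 (camera adjusted p = 0.449). In that list the flap endonuclease FEN1 fell by 1.74 ± 0.08, the uracil glycosylase UNG by 1.77 ± 0.08 and PARP1 by 0.56 ± 0.06 on the log2 scale. Of 16 end joining genes 3 rose and 4 fell, median -0.15 (camera adjusted p = 0.374), with RIF1 at -0.79 ± 0.11, SHLD2 at -0.37 ± 0.06 and POLM at 0.44 ± 0.07. Of 14 genes of translesion synthesis 7 fell and 1 rose, median -0.19 (camera adjusted p = 0.105), with USP1 at -0.88 ± 0.07, RAD18 at -0.82 ± 0.07 and POLH at -0.59 ± 0.08. Without a filter on low counts the translesion list was called lower (median -0.23, camera adjusted p = 0.00691). Adjusted over the list alone, the numbers lower were 8, 8, 5 and 7 in these 4 lists, and the numbers higher 9, 6, 3 and 1.

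All 29 measured targets of ATF4, the transcription factor of the integrated stress response, rose under sunitinib, with a median of 1.09 (camera adjusted p = 1.2e-18). PCK2 went from 21.5 ± 0.98 to 120.3 ± 7.32 CPM (SD, n = 3) and STC2, a secreted glycoprotein, rose by 1.65 ± 0.07. Among inflammatory genes under NF-kappaB 10 of 23 rose and 1 fell, median 0.34 (camera adjusted p = 0.00163), with IL6 at 3.25 ± 0.23, at 1.11 CPM in DMSO, and IL1A at 1.26 ± 0.10. Cholesterol synthesis genes rose in 11 of 25 cases and fell in 1, median 0.24 (camera adjusted p = 4.76e-04), with TM7SF2 at 1.56 ± 0.15, MVD at 0.64 ± 0.08 and INSIG1 at 0.51 ± 0.06. Without sunitinib replicate 3, camera with an estimated correlation did not call the inflammatory or the cholesterol list. Ribosome biogenesis and MYC target genes fell in 21 of 30 cases and rose in 1, median -0.42 (camera adjusted p = 7.43e-06), with UTP20 at -0.98 ± 0.10, RRS1 at -0.60 ± 0.07 and DDX21 at -0.52 ± 0.06. With p-values adjusted over the list alone, 29 ATF4 targets, 11 inflammatory genes and 11 cholesterol genes were higher, and 22 ribosome biogenesis genes lower. With an estimated correlation the camera adjusted p of the ATF4 list was 0.00268.

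Other list calls under sunitinib were lost with an estimated correlation. Heat shock genes fell in 15 of 17 cases, median -0.56 (camera adjusted p = 2.95e-07; adjusted p = 0.278 with an estimated correlation), with HSP90AA1 at -0.87 ± 0.09, CHORDC1 at -0.82 ± 0.08 and HSPA1A at -0.78 ± 0.07. Targets of p53 rose in 12 of 26 cases and fell in 1, median 0.25 (camera adjusted p = 0.00305; adjusted p = 0.0753 with an estimated correlation), led by GDF15 (1.80 ± 0.08), SESN2 (1.09 ± 0.09) and TP53I3 (0.90 ± 0.09). GDF15 and SESN2 are also induced by ATF4. Replication-dependent histone transcripts, most of which lack a poly(A) tail, were measured for 16 genes on polyadenylated RNA. Of these 9 rose and 1 fell, median 0.96 (camera adjusted p = 0.00394; adjusted p = 0.226 with an estimated correlation), with HIST1H2AC at 1.61 ± 0.12, HIST1H2BD at 1.52 ± 0.18 and HIST1H2BK at 1.03 ± 0.10. Without a filter on low counts the histone list was not called (median 0.40, camera adjusted p = 0.0926). In counts adjusted over the list alone, 15 heat shock genes were lower, and 12 p53 targets and 11 histone genes were higher.

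Ribosomal protein genes rose in 22 of 76 cases and fell in 1, median 0.40 (camera adjusted p = 8.68e-05; adjusted p = 0.745 with an estimated correlation). RPL28 changed by 0.50 ± 0.09, RPL3 by 0.45 ± 0.10 and RPL13A by 0.43 ± 0.12. When adjusted over the list alone, 2 were higher. The list moved with sunitinib replicate 3, without which its median was 0.11, with 42 genes higher and 4 lower. RPL13A was not called without DMSO replicate 1 (edgeR adjusted p = 0.0561) or without DMSO replicate 3 (edgeR adjusted p = 0.0531), and its value was 0.25 without sunitinib replicate 3. The 13 mitochondrial transcripts had a median of 0.28 (camera adjusted p = 0.142), with 3 higher, and a median of 0.08 without that library. They were called without sunitinib replicate 1 (camera adjusted p = 0.0181) or 2 (0.0347).

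Of 17 kinases that sunitinib is known to bind, 10 passed the count filter, and 6 fell and 1 rose (camera adjusted p = 0.0164; adjusted p = 0.174 with an estimated correlation). Their median was -0.34, and adjusted over the list alone 7 were lower and 1 higher. The main receptor targets were scarce or filtered out, KDR at 0.84 ± 0.22 CPM and PDGFRB at 0.73 ± 0.36 CPM in DMSO (SD, n = 3). AURKB, a mitotic kinase, changed by -0.97 ± 0.07, STK26 by -0.51 ± 0.08, MET by -0.51 ± 0.10, PRKAA2 by -0.37 ± 0.08 and PRKAA1 by -0.35 ± 0.06. STK10 rose by 0.41 ± 0.09. FGFR1 (-0.32 ± 0.09, edgeR adjusted p = 0.0171) was not called without DMSO replicate 3 (edgeR adjusted p = 0.0645) or with library totals as the scaling (edgeR adjusted p = 0.0727), and its value was -0.21 without sunitinib replicate 3. AXL, at 1110 ± 17.1 CPM in DMSO, had a value of -0.33 ± 0.13 (edgeR adjusted p = 0.0579), and was called when sunitinib replicate 1, 2 or 3 was left out, at -0.42, -0.43 and -0.16 (edgeR adjusted p = 0.0324, 0.0247 and 7.01e-05). With all 9 libraries AXL was called by DESeq2 at -0.35 (adjusted p = 0.0301) and with the length and GC correction at -0.34 (edgeR adjusted p = 0.00741). That correction narrows the spread but leaves sunitinib replicate 3 in the group mean.

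Compound 32 raised hypoxia and glycolysis genes and lowered mitotic genes. Against DMSO the largest rises were in ANGPTL4 (3.60 ± 0.17), a secreted lipase inhibitor, CXCR4 (3.57 ± 0.22), the receptor of the chemokine CXCL12, and BNIP3 (2.88 ± 0.16), a mitophagy receptor. PFKFB4 (2.81 ± 0.10), NDRG1 (2.56 ± 0.06), RASSF4 (2.49 ± 0.13), TCAF2 (2.22 ± 0.18) and the glucose transporter gene SLC2A1 (2.13 ± 0.09) followed. The steepest falls were in the helicase gene PIF1 (-3.54 ± 0.18), H1F0 (-2.01 ± 0.10), a linker histone, and KIF20A (-2.00 ± 0.09), a kinesin of cytokinesis. PLK1 (-1.99 ± 0.06), CCNB1 (-1.97 ± 0.12) and AURKA (-1.70 ± 0.08), drivers of mitotic entry, HIST1H2AC (-1.89 ± 0.15) and CCNA1 (-1.73 ± 0.20) completed the list. In edgeR, the adjusted p of all these genes was at most 1.54e-04, that of CCNA1.

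In total, edgeR called 1830 genes higher and 1571 lower under compound 32, 22.3% of the genes tested. At 2-fold or more these were 306 and 174. Without sunitinib replicate 3, which belongs to neither group compared but takes part in the count filter, the scaling and the estimate of the spread, 3359 genes were higher and 3189 lower. With only the 6 libraries compared, the counts were 3258 and 3114. Without DMSO replicate 1, 2 or 3 there were 1206, 1204 and 1168 genes higher and 1035, 1036 and 968 lower. Without compound 32 replicate 1, 2 or 3 there were 993, 1006 and 969 lower, and 1176 higher without the third.

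All 30 measured genes of hypoxia and glycolysis rose under compound 32, with a median of 1.37 (camera adjusted p = 1.27e-31). NDRG1 went from 133 ± 3.00 to 786.1 ± 15.6 CPM (SD, n = 3), the glycolytic enzyme gene ENO2 rose by 2.00 ± 0.07 and KDM3A, an oxygen-dependent histone demethylase, by 1.72 ± 0.06. NDRG1 (ENSG00000104419) lies on chromosome 8 from 133237171 to 133302022, CXCR4 (ENSG00000121966) on chromosome 2 from 136114349 to 136118165 and PLK1 (ENSG00000166851) on chromosome 16 from 23677656 to 23690367 (GRCh38). Mitotic genes fell in 32 of 39 cases and rose in 1, median -0.63 (camera adjusted p = 3.22e-18), with CDC20 at -1.45 ± 0.07. In contrast, 27 of 35 genes of DNA replication and S phase rose and 0 fell, median 0.50 (camera adjusted p = 2.11e-15). The cyclin gene CCNE2 rose by 1.84 ± 0.10, RRM2 by 1.11 ± 0.08 and E2F1 by 0.92 ± 0.07. The exons of CCNE2 overlap those of INTS8, which had a value of -0.09 ± 0.08. Adjusted over the list alone, 30 hypoxia genes and 29 S phase genes were higher, and 33 mitotic genes lower with 2 higher. With an estimated correlation the camera adjusted p was 3.63e-04 for hypoxia, 0.0117 for S phase and 0.0281 for mitosis.

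Targets of p53 rose in 19 of 26 cases and fell in 1, median 0.48 (camera adjusted p = 4.22e-10). They were led by CDKN1A (1.28 ± 0.07), an inhibitor of cyclin-dependent kinases, GDF15 (1.39 ± 0.08) and TP53INP1 (1.01 ± 0.08). Histone transcripts fell in 11 of 16 cases and rose in 0, median -1.43 (camera adjusted p = 9.19e-09), with HIST2H2BE at -1.73 ± 0.23 and HIST1H2BJ, at 2.18 CPM in DMSO, at -2.31 ± 0.32. Ribosome biogenesis genes fell in 14 of 30 cases and rose in 0, median -0.32 (camera adjusted p = 1.3e-06), with RRS1 at -1.10 ± 0.07, RRP9 at -0.73 ± 0.07 and DDX21 at -0.47 ± 0.06. Cholesterol synthesis genes rose in 13 of 25 cases and fell in 0, median 0.25 (camera adjusted p = 4.57e-05), with STARD4 at 0.94 ± 0.06, HMGCS1 at 0.63 ± 0.06 and IDI1 at 0.85 ± 0.10. With p-values adjusted over the list alone, 19 p53 targets were higher and 13 histone genes lower. Likewise 17 ribosome biogenesis genes were lower, and 14 cholesterol genes higher with 1 lower.

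Feedback and immediate early genes of ERK signalling rose in 13 of 23 cases and fell in 2, median 0.36 (camera adjusted p = 5.31e-05). DUSP5 rose by 0.95 ± 0.06 and EPHA4 by 1.55 ± 0.11, while FOSL1 fell by 0.81 ± 0.07. Inflammatory genes under NF-kappaB rose in 13 of 23 cases and fell in 1, median 0.39 (camera adjusted p = 1.40e-04), with IL11 at 1.90 ± 0.14, TNFAIP3 at 1.19 ± 0.09 and CSF2, at 0.38 CPM in DMSO, at 3.17 ± 0.34. Without sunitinib replicate 3, camera with an estimated correlation called neither this list nor that of cholesterol synthesis. Regulators of apoptosis rose in 12 of 30 cases and fell in 0, median 0.21 (camera adjusted p = 4.07e-04; adjusted p = 0.0751 with an estimated correlation), with APAF1 at 0.83 ± 0.10, BBC3 at 0.82 ± 0.10 and PMAIP1 at 0.66 ± 0.09. In counts adjusted over the list alone, 15, 14 and 14 members of these lists were higher, and 3, 1 and 0 lower.

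The list of all DNA repair pathways was not called under compound 32, with 37 of 142 members higher, 14 lower and a median of 0.09 (camera adjusted p = 0.0807). When adjusted over the list alone, 42 were higher and 19 lower. Homologous recombination and Fanconi anaemia genes rose in 18 of 46 cases and fell in 3, median 0.21 (camera adjusted p = 4.07e-04). BRIP1 rose by 1.01 ± 0.07 and RMI1 by 0.53 ± 0.07, and FANCF fell by 1.09 ± 0.14. Mismatch repair genes rose in 9 of 18 cases and fell in 1, median 0.23 (camera adjusted p = 0.0418; adjusted p = 0.25 with an estimated correlation), with EXO1 at 0.99 ± 0.14, PCNA at 0.77 ± 0.11 and POLD3 at 0.44 ± 0.07. That call was lost when DMSO replicate 1 (camera adjusted p = 0.0624), DMSO replicate 3 (0.0677), compound 32 replicate 1 (0.0538) or compound 32 replicate 3 (0.0563) was left out. A block for the number in the sample titles also ended it (camera adjusted p = 0.0537). Adjusted over the list alone, 21 homologous recombination genes and 9 mismatch repair genes were higher, with 4 and 1 lower.

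The other repair lists were not called under compound 32. Checkpoint genes had a median of -0.12, with 3 higher and 6 lower (camera adjusted p = 0.806), among them CLSPN at 0.73 ± 0.07, CDC25A at 0.77 ± 0.08 and H2AFX at -0.69 ± 0.10. Nucleotide excision repair had a median of -0.09, with 5 higher and 4 lower (camera adjusted p = 0.806), and its member DDB2, a p53 target, rose by 0.79 ± 0.08. Base excision repair had a median of -0.05, with 3 higher and 3 lower (camera adjusted p = 0.965), including FEN1 at 0.56 ± 0.07 and LIG3 at -0.94 ± 0.10. End joining had a median of -0.11, with 0 higher and 3 lower (camera adjusted p = 0.233), which were SHLD2 (-0.49 ± 0.06), DCLRE1C (-0.57 ± 0.11) and LIG4 (-0.44 ± 0.09). Translesion synthesis had a median of 0.15, with 3 higher and 0 lower (camera adjusted p = 0.0807), which were POLH (0.84 ± 0.08), USP1 (0.40 ± 0.07) and RAD18 (0.35 ± 0.07). With p-values adjusted over the list alone, the numbers higher and lower were 5 and 7, 6 and 7, 4 and 4, 0 and 3, and 3 and 0 in these 5 lists. Of the kinases bound by sunitinib, AXL changed by -0.65 ± 0.13 and the list was not called, with a median of -0.11 (camera adjusted p = 0.727), and -0.01 over 11 members without sunitinib replicate 3.

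In the direct comparison of the compounds, S phase genes had the smallest camera p and histone transcripts the largest median difference. By mean log2 CPM these lists were close, at 2.01 for S phase genes and -1.97 for histone transcripts. All 35 S phase genes were higher under compound 32 than under sunitinib, with a median of 1.74 (camera adjusted p = 3.63e-26). The largest differences in the higher direction were in CXCR4 (5.56 ± 0.28), E2F2 (4.45 ± 0.22), ANGPTL4 (4.23 ± 0.18), FAM111B (4.15 ± 0.10), CCNE2 (3.89 ± 0.12), E2F8 (3.64 ± 0.11), ZNF367 (3.16 ± 0.10) and RRM2 (3.11 ± 0.09). In the lower direction they were in HIST1H2AC (-3.50 ± 0.14), SLC6A9 (-2.95 ± 0.18), LURAP1L (-2.94 ± 0.18), PCK2 (-2.88 ± 0.09), H1F0 (-2.84 ± 0.10), ASS1 (-2.84 ± 0.19), PIF1 (-2.77 ± 0.19) and CCDC92 (-2.54 ± 0.14). E2F1 (2.88 ± 0.07), DTL (2.72 ± 0.07), ATAD2 (2.78 ± 0.07) and MYBL2 (2.46 ± 0.07) differed with opposite calls against DMSO. In edgeR, the adjusted p of the genes named here was at most 4.47e-07, that of PIF1. CXCR4 was scarce, at 0.25 to 0.78 CPM in the sunitinib libraries and 1.35 to 2.76 CPM in DMSO. Its difference between the compounds was 6.04 without sunitinib replicate 3. In total, 3664 genes were higher and 3834 lower under compound 32 than under sunitinib, and at 2-fold or more 820 and 1230. Upper-quartile factors moved the split to 3008 and 4712. The doses of the compounds are not known to match.

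Hypoxia and glycolysis genes were higher under compound 32 in 29 of 30 cases, median 1.30 (camera adjusted p = 5.58e-17), with HK2 at 2.17 ± 0.09. ATF4 targets were lower in 26 of 29 cases and higher in 2, median -0.93 (camera adjusted p = 6.58e-11), with TRIB3 at -1.85 ± 0.07 and PHGDH at -1.22 ± 0.07. Homologous recombination genes were higher in 31 of 46 cases and lower in 5, median 1.03 (camera adjusted p = 4.99e-09), with BRIP1 at 2.63 ± 0.08, XRCC2 at 2.04 ± 0.09 and RMI1 at 1.73 ± 0.07. Checkpoint genes were higher in 12 of 21 cases and lower in 1, median 0.43 (camera adjusted p = 2.63e-04), with CLSPN at 2.97 ± 0.08. In counts adjusted over the list alone, 35 S phase, 29 hypoxia, 32 homologous recombination and 12 checkpoint genes were higher, and 27 ATF4 targets lower.

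All repair pathways together were higher in 63 of 142 cases and lower in 30, median 0.16 (camera adjusted p = 2.63e-04; adjusted p = 0.0802 with an estimated correlation), 0.28 without sunitinib replicate 3, 0.10 with library totals as the scaling and 0.07 with upper-quartile factors. When adjusted over the list alone, 64 were higher and 32 lower. Mismatch repair genes were higher in 11 of 18 cases and lower in 2, median 0.84 (camera adjusted p = 2.91e-04; adjusted p = 0.0802 with an estimated correlation), with MSH6 at 1.64 ± 0.06. Translesion synthesis genes were higher in 7 of 14 cases and lower in 1, median 0.33 (camera adjusted p = 0.028; adjusted p = 0.129 with an estimated correlation), with POLH at 1.43 ± 0.08. Histone transcripts were lower in 13 of 16 cases, median -1.93 (camera adjusted p = 4.88e-07; adjusted p = 0.0786 with an estimated correlation). Heat shock genes were higher in 13 of 17 cases, median 0.45 (camera adjusted p = 1.25e-04; adjusted p = 0.536 with an estimated correlation), with BAG3 at 0.66 ± 0.06. Ribosomal protein genes were lower in 33 of 76 cases, median -0.41 (camera adjusted p = 1.81e-04; adjusted p = 0.841 with an estimated correlation), and -0.13 without sunitinib replicate 3. Adjusted over the list alone, 11 mismatch repair, 7 translesion and 14 heat shock genes were higher, and 14 histone and 29 ribosomal protein genes lower.

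Lists that camera did not call between the compounds differed by various amounts. The difference of mean log2 CPM, compound 32 minus sunitinib, was -0.02 for nucleotide excision repair (95% interval -0.10 to 0.06) and -0.01 for end joining (-0.10 to 0.08). It was -0.01 for cholesterol synthesis (-0.06 to 0.04) and 0.04 for ribosome biogenesis (-0.06 to 0.13). For mitotic genes it was 0.17 (0.06 to 0.28), where camera did not call the list (camera adjusted p = 0.215) except without a filter on low counts (camera adjusted p = 0.0321). Within it, PLK1 (-0.94 ± 0.06) was lower and ANLN (1.04 ± 0.07) higher under compound 32. The difference was larger for ERK feedback genes at 0.40 (0.33 to 0.46), epithelial markers at -0.66 (-1.01 to -0.32), Mullerian and serous markers at 0.36 (0.22 to 0.51), NRF2 targets at -0.26 (-0.33 to -0.18) and apoptosis regulators at 0.24 (0.14 to 0.34). Without sunitinib replicate 3 the list medians between the compounds moved from -0.65 to -0.34 for epithelial markers, from -0.12 to -0.03 for NRF2 targets, from 0.18 to 0.28 for mitotic genes, from 0.04 to 0.13 for ribosome biogenesis and from -0.004 to 0.10 for cholesterol synthesis. The apoptosis list (camera adjusted p = 0.0533) was called without sunitinib replicate 3 (camera adjusted p = 0.0246), and without compound 32 replicate 1 (0.0395) or 2 (0.0347). The ERK list (camera adjusted p = 0.0941) was called without a filter on low counts (camera adjusted p = 0.00204).

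**Figure D1:**
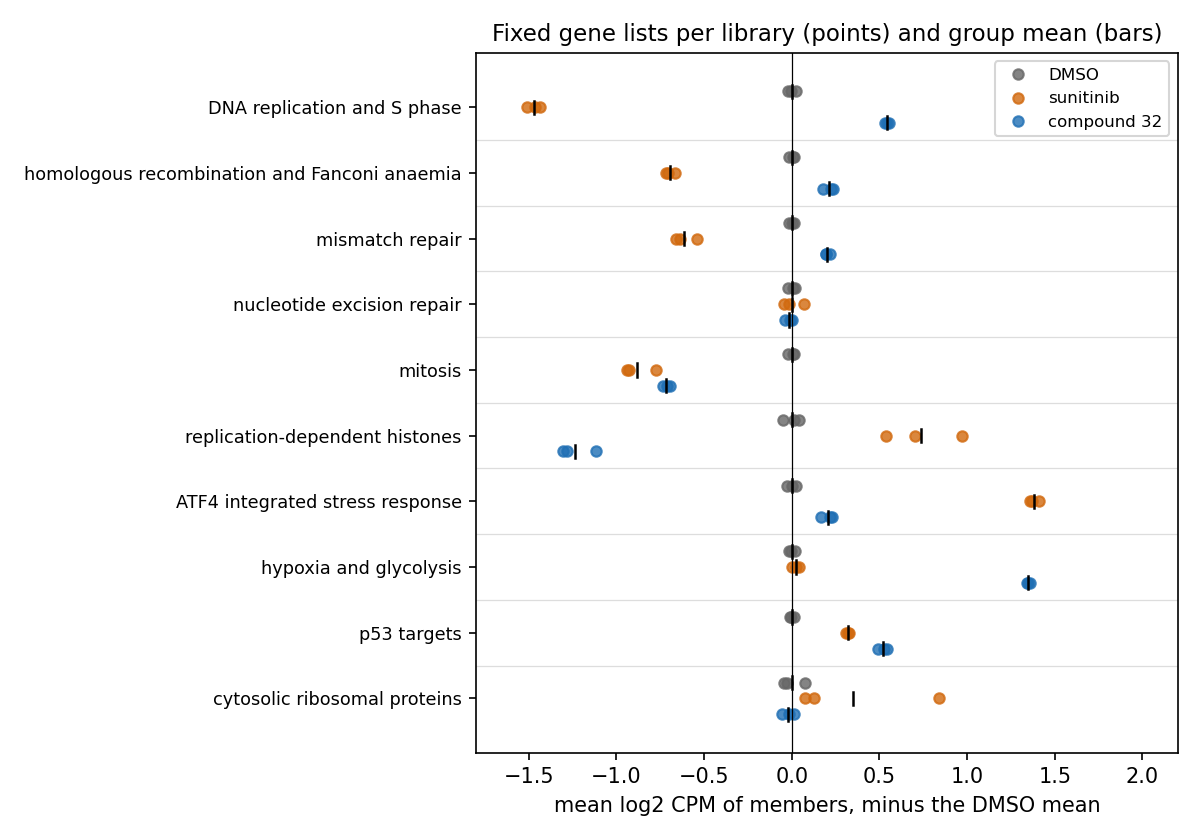
Mean log2 CPM over the members of 10 fixed gene lists, minus the mean of the DMSO libraries (x axis), with 1 point per library and a bar at each group mean. The sunitinib and compound 32 libraries lie on opposite sides of DMSO for S phase, homologous recombination, mismatch repair and histone genes, and on the same side for mitosis.

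Across genes, the log2 fold changes of the compounds against DMSO were close to uncorrelated, with a Pearson r of 0.03 and a Spearman rho of 0.03 over 15232 genes, which are not independent replicates. Both share the DMSO libraries, and 20 simulations of unchanged groups against those controls gave a mean r of 0.507 and a mean covariance of 0.0242. The observed covariance was 0.00913, a difference of -0.015. The simulated and observed r are not comparable, because the simulated fold changes hold only noise and the observed ones also hold the responses to the compounds. The correlation was 0.09, 0.11 and 0.13 without DMSO replicate 1, 2 or 3, 0.05 without sunitinib replicate 3, 0.01 among genes with a mean of at least 10 CPM and 0.39 without a filter on low counts. Both compounds raised 397 genes, against 371 for independent lists, and lowered 569, against 313. Sunitinib raised and compound 32 lowered 290 genes, against 319, and sunitinib lowered and compound 32 raised 557, against 365. All 290 and 557 were also called in the direct comparison, which was nearly fixed in advance for genes with opposite calls against the same controls. The controls were not split, since a part would hold 1 library, so part of any excess of genes moved in the same direction may come from the shared controls.

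**Figure D2:**
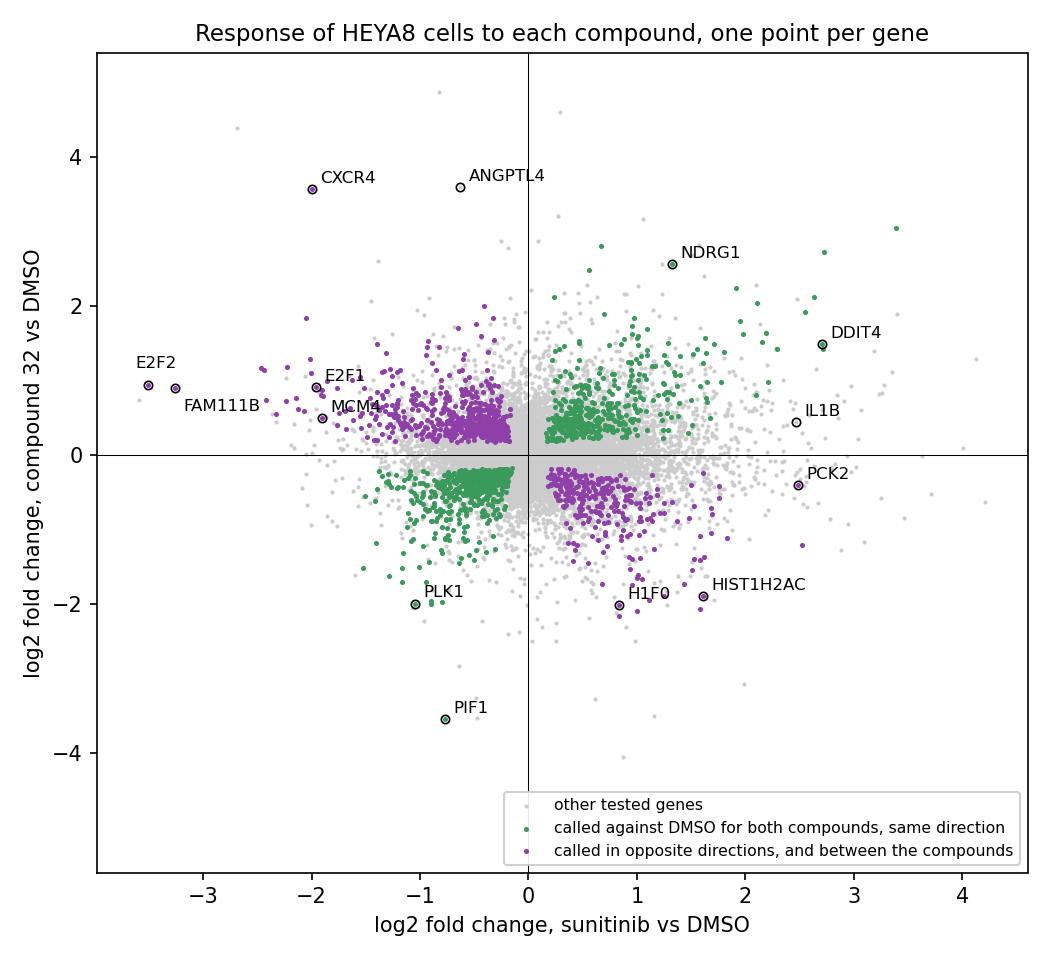
Log2 fold change of each of 15232 tested genes under sunitinib (x axis) and compound 32 (y axis), both against DMSO. Green points are the 397 and 569 genes called in the same direction for both compounds, purple points the 290 and 557 called in opposite directions, and circles mark named genes.

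**Figure D3:**
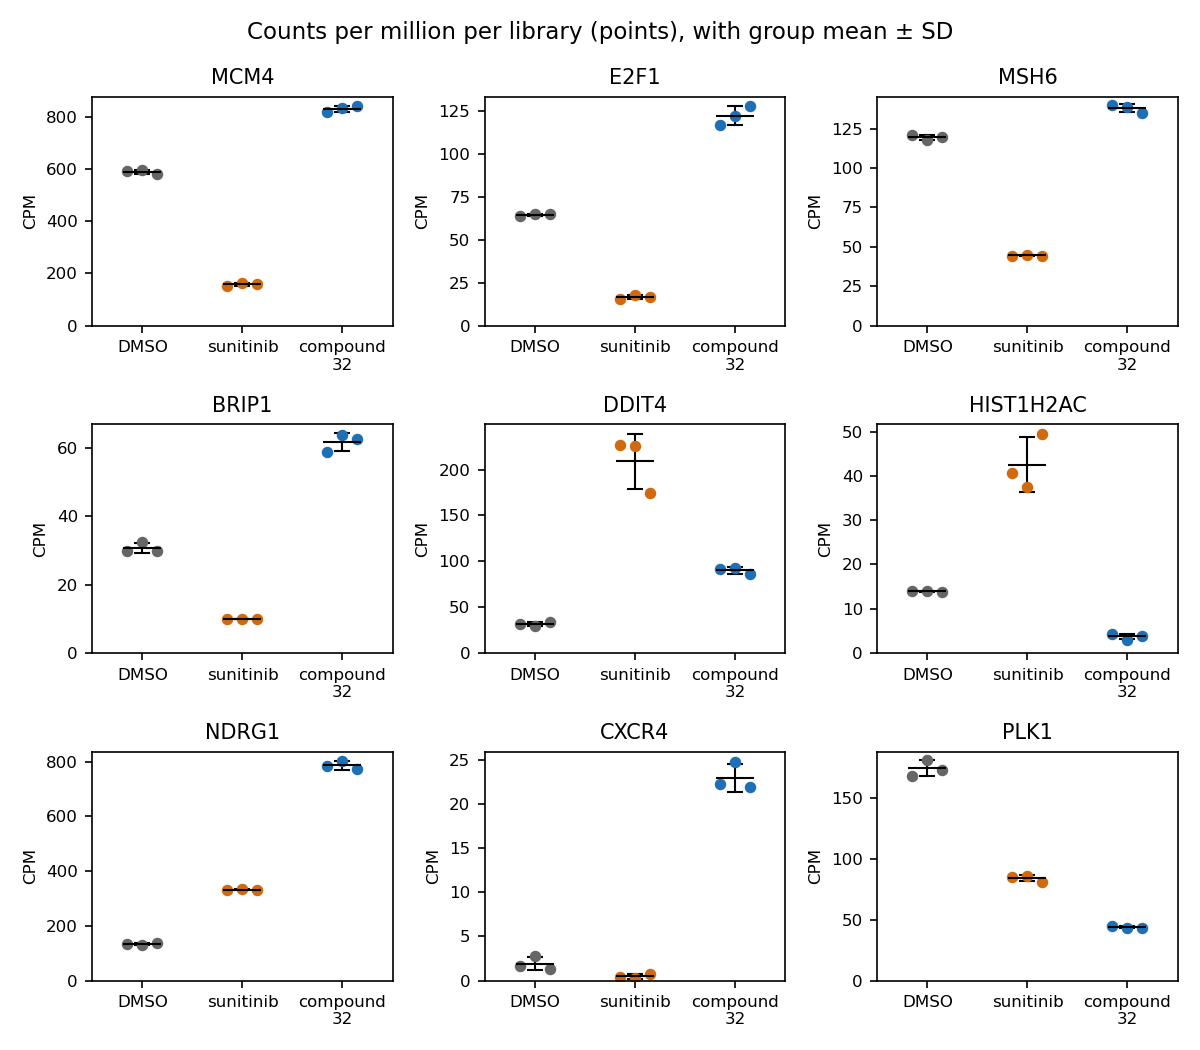
TMM-scaled CPM (y axis) of 9 genes in each library, with the group mean and SD (n = 3). MCM4, E2F1, MSH6 and BRIP1 are lowest under sunitinib and highest under compound 32, and HIST1H2AC shows the reverse order.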

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

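Among the tests in this part, 3 were chosen only after the result was seen. These are the test of library scaling for the hypoxia genes, the division of the DNA repair genes by their link to S phase, and the DNA repair list without sunitinib replicate 3.

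The compounds moved several gene groups in opposite directions against DMSO. The groups given here were chosen because camera called them in all 3 comparisons. Their calls in the direct comparison of compound 32 with sunitinib are therefore no separate support. The median log2 difference was 1.738 for DNA replication and S phase, 1.032 for homologous recombination and Fanconi anaemia, 0.844 for mismatch repair and -1.934 for replication-dependent histones. The last 2 were not called with an estimated correlation (adjusted p = 0.0802 and 0.0786), but were without sunitinib replicate 3 (adjusted p = 0.0403 for each). Nor were the rise of histones under sunitinib (adjusted p = 0.226) and that of mismatch repair under compound 32 (adjusted p = 0.25). Sunitinib raised and compound 32 lowered 290 genes, and sunitinib lowered and compound 32 raised 557 genes.

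With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every split but the real one mixes both treatments in each part. A treatment effect then widens the spread within the parts, so few calls in those splits do not measure what chance alone gives. The real split of sunitinib and DMSO called 6126 genes and the highest of the others 0, so 1 split of 10 gave as many. The real split of compound 32 and DMSO called 3401 and the highest other 0, and that of compound 32 and sunitinib called 7498 and the highest other 0, again 1 of 10 each.

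Sunitinib replicate 3 stood apart from replicates 1 and 2. Across 7930 genes called without it, the deviation of replicate 3 ran against the change in the other replicates. The slope was -0.11 (bootstrap SD 0.0073), under the bound of 0.1 set beforehand for a stronger response, and -0.082 and -0.094 where no library was shared. Choosing genes called from replicates 1 and 2 pulls these slopes down. On the first principal component replicate 3 lay further from DMSO (-12.72 to -10.64), at 56.06 against 45.06 and 44.98. The slopes showed no stronger response across these genes, but cannot exclude one in replicate 3. Its deviation went with gene length (Spearman rho = -0.337, highest of the other libraries 0.292), so a gene length bias, such as RNA of lower quality gives, is a candidate explanation, although replicates 1 and 2 are measured against replicate 3 and do not give independent values. Length and GC content were not the whole cause, because the SD of the deviation was 0.38 after their trend was taken out, against at most 0.228 in the DMSO and compound 32 libraries. What else set this library apart stays open, and a biological difference was not tested.

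Compound 32 raised all 30 hypoxia and glycolysis genes. A trend with gene length and GC content was argued against by a median of 1.349 (SD 0.19) once it was taken out. The list's median lay 1.366 (SD 0.17) above that of all tested genes. Library scaling moves all genes of a library alike and cancels from this difference, so the test could not have pointed to scaling. It shows only that the list rose relative to other genes. The transcript of TFRC, the transferrin receptor, is stabilised when iron is short, and it rose by 0.712 ± 0.077 under compound 32, past the bound of 0.5 set beforehand. Less iron available to the cells may therefore have contributed, as a hypothesis, but TFRC is also raised by hypoxia signalling itself, and oxygen in the cultures was not measured.

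The DNA repair list fell under sunitinib. Sunitinib replicate 3 alone was argued against by a median of -0.308 (SD 0.054) without it, and a trend with gene length and GC content by a median of -0.213 (SD 0.051) once it was taken out. Of the 41 of 142 repair genes known to peak with S phase 37 fell and 0 rose, median -1.098, while of the others 27 fell and 22 rose, median -0.092 (SD 0.048). The fall may thus follow that of genes that cycle with S phase, as a hypothesis, with the median less than 1 SD from its bound of -0.1. Under compound 32 the same parts had medians of 0.395 and -0.058, and whether fewer cells were in S phase was not measured.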

How the results depend on the processing

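Chosen after seeing the data were the within-group length and GC correction, the 8 libraries other than sunitinib replicate 3, and upper-quartile factors for the lists. All 114 list results kept their side of the threshold with library totals, upper-quartile factors and a prior count of 0.5, and called lists kept their direction. The direction of lists that were not called was not compared. For the scalings this outcome was nearly fixed in advance. A scaling factor moves all genes of a library alike, and camera compares a list with the other genes. RLE factors and only the 6 libraries compared each gained 1 call. The length and GC correction gained 3 calls, of mitochondrial transcripts under sunitinib (adjusted p = 0.0146), extracellular matrix genes under compound 32 (0.0209) and apoptosis regulators between the compounds (0.0381). Since it leaves group means in place, these calls reflect a narrower spread. The mitochondrial median was 0.274 with it and 0.28 without it, so any bias of sunitinib replicate 3 in that mean remained. Without a filter on low counts 5 were gained and 1 lost. With an estimated correlation 13 calls were lost. The same test without sunitinib replicate 3 called heat shock under sunitinib (adjusted p = 0.0354) and all repair (0.0212), mismatch repair (0.0403) and histones (0.0403) between the compounds. It did not call cholesterol synthesis (0.11 and 0.0736) or NF-kappaB genes (0.117 and 0.118) under sunitinib and compound 32, which it had called with all 9 libraries. With fry, which does not compare a list with other genes, 2 were lost, 33 gained, and the hypoxia list under sunitinib (median -0.036) was called higher (adjusted p = 0.0053), where camera had not called it. Where a value moved, the cause was not tested, except that stricter thresholds pass fewer genes.

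At a log2 fold change of at least 1, genes higher and lower numbered 864 and 339 for sunitinib vs DMSO, 306 and 174 for compound 32 vs DMSO and 820 and 1230 for compound 32 vs sunitinib. At an adjusted p under 0.01 they were 1857 higher for sunitinib, and 977 and 738 for compound 32 vs DMSO. For compound 32 vs DMSO, only the 6 libraries compared gave 3258 and 3114, the 8 libraries 3359 and 3189, and the length and GC correction 2395 lower. Leaving out 1 of the 6 libraries compared gave 2276 to 3908 higher and 2462 to 4096 lower for sunitinib, 1168 to 1221 and 968 to 1036 for compound 32 vs DMSO, and 3183 to 4620 and 3168 to 4519 between the compounds.

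The DNA repair list kept its median of 0.093 under compound 32 with fry, which called it (adjusted p = 0.00399), and its median of 0.157 between the compounds was not called with an estimated correlation (adjusted p = 0.0802). Leaving out 1 library gave -0.308 to -0.201, 0.075 to 0.104 and 0.143 to 0.275 in the 3 comparisons. The correlation between the compounds was 0.394 without a filter on low counts, and 0.025 to 0.13 when 1 library was left out.

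Samples share a number across groups, and the count columns of sunitinib and compound 32 also share the letters A, B and C. Deviations of same-numbered samples correlated at -0.08 to 0.06, which gave no sign of pairing but cannot exclude it. The replicate block gave 2846 and 2912 genes for sunitinib, 1559 and 1319 for compound 32 vs DMSO and 3535 and 3639 between the compounds. With it the mismatch repair list (camera adjusted p = 0.0537) and AURKB (edgeR adjusted p = 0.0707) were not called for compound 32 vs DMSO, and no other call changed among the 114 list and 209 gene results run with it. AURKB (-0.20) was also not called without any 1 of the DMSO or compound 32 replicates, PRKAA2 without DMSO replicate 2 or compound 32 replicate 1, and MET without compound 32 replicate 3. Without sunitinib replicate 3 these genes were called for compound 32 vs DMSO. Their values were then -0.203 for AURKB (edgeR adjusted p = 8.77e-04), 0.328 for PRKAA2 (1.81e-05) and -0.402 for MET (8e-14).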

Other observations

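Replication-dependent histones had medians of 0.96 under sunitinib and -1.43 under compound 32, where S phase genes had -1.39 and 0.50. The sunitinib value was not called with an estimated correlation (adjusted p = 0.226) or without a filter on low counts (median 0.40, camera adjusted p = 0.0926). The next genes were chosen after their values were seen and belong to no fixed list of histone regulators. SLBP, which binds the stem-loop of histone transcripts, fell by 0.76 ± 0.10 on the log2 scale under sunitinib and rose by 0.36 ± 0.10 under compound 32. NPAT, which activates histone transcription, fell by 0.63 ± 0.08 and rose by 0.41 ± 0.08. TFRC fell by 0.90 ± 0.08 under sunitinib. VEGFA rose under both, by 1.51 ± 0.07 and 1.37 ± 0.07, although the hypoxia list was not called under sunitinib (median -0.04, mean 0.03, camera adjusted p = 0.656). Of the 30 members of that list 6 rose and 9 fell under sunitinib. NDRG1 lay at 131 to 136 CPM in the DMSO libraries and at 330 to 335 CPM in the sunitinib libraries.

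The next fixed lists were not called by camera in any comparison of all 9 libraries with TMM factors. Single members still moved under sunitinib, where 40.2% of all tested genes were called. Higher and lower were 15 and 8 of 39 interferon genes and 7 and 3 of 25 NRF2 targets. For lysosome and autophagy genes these numbers were 13 and 8 of 44. Medians against DMSO are given for sunitinib and then for compound 32. They were 0.27 and 0.08 for the interferon response, 0.14 and -0.03 for NRF2 targets, -0.14 and 0.11 for YAP and TEAD targets, and 0.09 and 0.05 for lysosome and autophagy genes. They were -0.09 and -0.06 for endoplasmic reticulum chaperones, 0.12 and 0.04 for fatty acid synthesis, 0.14 and 0.06 for oxidative phosphorylation, and -0.04 and 0.17 for extracellular matrix genes. The extracellular matrix list (camera adjusted p = 0.0533 for compound 32) was called with the length and GC correction (0.0209), without sunitinib replicate 3 (0.0227), without compound 32 replicate 3 (0.0498) and with only the 6 libraries compared (0.0267). Fatty acid synthesis genes were called between the compounds without sunitinib replicate 3 (median -0.24, camera adjusted p = 0.0246). Platinum and drug transport genes had 0.26 and 0.04, and aryl hydrocarbon receptor targets 0.17 and -0.28. Markers had 0.62 and -0.28 for epithelium, -0.08 and 0.28 for endothelium, -0.39 and 0.02 for fibroblasts and pericytes, -0.05 and 0.07 for leukocytes, and -0.26 and 0.05 for Mullerian and serous ovarian cancer.

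Without sunitinib replicate 3 several of the sunitinib medians moved by over 1.5 times. They were -0.05 for oxidative phosphorylation, 0.15 for the interferon response, 0.03 for NRF2 targets, -0.04 for YAP and TEAD targets and 0.04 for lysosome and autophagy genes. They were 0.12 for platinum and drug transport, 0.11 for aryl hydrocarbon receptor targets, -0.24 for endothelium, 0.03 for leukocytes, -0.10 for hypoxia and glycolysis and -0.07 for apoptosis regulators. For oxidative phosphorylation 12 genes were then higher and 18 lower, and the mean log2 CPM of the list, minus that of DMSO, was 0.473 in replicate 3 against -0.035 and -0.07 in the others.

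Lists called in some comparisons were not called in others. Under sunitinib, apoptosis regulators had a median of -0.04 (camera adjusted p = 0.989) and ERK feedback genes 0.18 (0.213). Under compound 32, ATF4 targets had a median of -0.05 and a mean of 0.20 (camera adjusted p = 0.447), heat shock genes a median of -0.06 (0.205) and ribosomal protein genes -0.02 (0.767). Mitochondrial transcripts, which the main list test called in no comparison, had a median of 0.09 under compound 32 (camera adjusted p = 0.654).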
